A study of Homo sapiens with 15 samples.

How the data were processed

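RNA from JIMT-1 cells, an established HER2-positive breast cancer line, was measured on a fixed gene panel, which the labels class as expression profiling by array. The medium held 10% fetal bovine serum, per the labels. HSL119 was given at 1 ug/ul and the knockdown lines were grown in 1 ug/ul puromycin, per the labels. Both concentrations are high for cell culture, and whether ug/ml was meant is not known. The labels give no treatment time and do not say whether CTL cells received vehicle, puromycin or a control shRNA. Groups were taken from the sample titles as HSL119 (n = 3), CTL (n = 4), KD1 (n = 4) and KD2 (n = 4).

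The deposited table holds, per the file headers, a block of log2 normalized counts and a block of linear normalized counts for the same libraries. The log2 values were used for the tests as deposited by the authors, who do not state their normalization. The linear block is a signal on the authors' scale, per the file headers a normalized linear count. Each library's linear values were multiples of a single step, so that the counts behind them could be recovered as whole numbers within 0.01. For HSL119 replicates 2 and 3 this recovery was less certain, since few values lay near the step, and no count model was run on HSL119. The log2 block differed from the log2 of the linear block by a constant per library, on average -0.155 in CTL and 0.172 in HSL119 and nil in the knockdowns. The deposited blocks therefore place CTL and HSL119 differently against the knockdowns, and the scale was varied for this reason. The value table of the series holds the same log2 values.

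Total recovered counts ran from 1241234 to 1561639 per library, and the 10 most abundant genes took 20.6% to 27.6% of them. These numbers limit the precision of low values. Gene symbols were compared with a RefSeq table of GRCh38.p14 for names alone: 749 of 758 were current and 9 were older symbols, such as HIST1H1C and RARRES3, and these are printed as the table gives them. No genome build is named for the panel, so no coordinates are given. HUNK is not on the panel, and no control or housekeeping probes are identified. A gene was tested when its linear value exceeded 20 in at least 3 of 15 libraries, which kept 622 and left out 136.

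Differences were tested in R 4.3.3 with limma 3.58.1, with all 15 libraries in a single fit of 4 groups, lmFit, contrasts and eBayes with a trend. P-values were two-sided and adjusted by Benjamini-Hochberg over the 622 genes with a threshold of 0.05. The contrasts were HSL119, KD1 and KD2 each against CTL, KD1 against KD2, and HSL119 against the mean of KD1 and KD2. The last was also read by 90% intervals against 1.5-fold. The gene lists, contrasts, filter, tests and the rule for named genes were fixed before the data were examined. That rule takes the 10 largest rises and falls against CTL among genes past the threshold with every treated library on the same side of the CTL mean, and the 5 largest each way in the other contrasts. It adds the 5 shared each way with the largest smallest change, and up to 4 members of each list with at least 3 called genes or a passing test. Further list members, the genes that passed in all 3 comparisons and the genes of opposite direction were named after their values were seen.

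The demand that a gene pass on 5 scalings was chosen after seeing the data. The scalings were the deposited log2 values, log2 of the linear value plus 1, centring on sample medians, quantile normalization and median of ratios. Each was fitted with all libraries and with libraries 1 and 2, and 3 and 4, of CTL, KD1 and KD2 averaged. This averaging was added because their recovered counts differed by little more than counting error, with a chi-square per degree of freedom of 1.54 and 1.15 in CTL and 1.15 and 1.32 in KD1. In KD2 it was 1.37 for libraries 1 and 2 but 23.8 for 3 and 4. Between the pairs of a group it lay at 5.47 to 5.63 in CTL and 135 to 174 in the knockdowns, and HSL119 libraries differed by 4.17 to 20.6. The labels do not say whether the pairs are technical repeats. Principal components, differences of replicates 3 and 4 from 1 and 2, and deviations from group means were computed on the median of ratios scale.

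Of 25 pathway lists, 23 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01, adjusted over the 23 within a contrast, and with fry. The lists cover ERBB, PI3K, MAPK, cell cycle, p53, apoptosis, DNA repair, epithelial, mesenchymal, luminal, basal, interferon, antigen presentation, NF-kB, secreted factors, JAK-STAT, TGF-beta, Wnt, Notch, hypoxia, glycolysis, chromatin and immune checkpoint genes. The autophagy list had 1 tested gene and the stress response list 3, and both are given by gene. Markers of 6 other cell types served as a check. Some genes that the naming rule or a list takes in are not reported here. Pairing by replicate number was checked by correlating, across genes, each library's deviation from its group mean. Deviations of equal number correlated at 0.594 to 0.764 between KD1 and KD2, at -0.214 to -0.007 between CTL and the knockdowns and at 0.018 to 0.128 between CTL and HSL119. The first pair of groups was therefore also fitted with a replicate block, beside the block over all libraries. Deviations of unequal number were not correlated. Pairing by single number was therefore not told apart from a difference between sets of libraries.

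Alternatives fixed beforehand were no filter, a floor of 50, 5 other scales or sources, the replicate block, eBayes without trend or robust, arrayWeights, the compared groups alone, a fold threshold of 1.5, an adjusted p under 0.01, camera with an estimated correlation, fry, and each library left out. Those chosen after seeing the data were median of ratios, pairs averaged, knockdown replicates 1 and 2 or 3 and 4 alone, the replicate block in the knockdowns alone, split controls, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered counts of CTL, KD1 and KD2. Overlaps were set against the number expected if HSL119's genes were drawn without regard to those shared by the knockdowns, and repeated with controls split by pair, and correlations against 200 simulated sets of unchanged groups with shared controls and all 6 splits of the controls. Gene length, from the RefSeq annotation, was regressed out of each library's log2 values as a linear trend on its log2 to test the shared rises. The procedure was tested on simulated data with 100 changed genes: at a true 2-fold change limma recovered between 87 and 92 of them on the deposited scale and between 73 and 89 on every scaling, and at 1.5-fold between 59 and 69, and 41 and 57. A shifted list was recovered in each of the 5 contrasts, and 0 of 20 other lists passed. Among unchanged genes at most 9 passed on the deposited scale and 1 on every scaling. The simulated noise was independent between libraries. It held no near-duplicate pairs, no difference within the knockdown lines, no shift of the whole panel and no offset between the blocks. These figures therefore do not show error control for libraries with that structure. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.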

Results

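RNA was measured with a fixed panel of 758 genes in JIMT-1, a human HER2-positive breast cancer cell line, on what the labels call an array platform. The 15 libraries fall into 4 groups. HSL119, a compound given here by its code name, was applied to 3 libraries. HUNK, a serine/threonine kinase, was targeted by shRNA in the lines KD1 (n = 4) and KD2 (n = 4). The reference group is CTL (n = 4). HUNK is not among the genes of the panel, so its own level was not measured. The total count recovered per library ran from 1241234 to 1457370 in CTL, from 1361855 to 1466439 in HSL119, from 1456002 to 1543047 in KD1 and from 1442964 to 1561639 in KD2. These totals limit the precision of genes near background, and 622 genes exceeded a linear value of 20 in at least 3 of the 15 libraries and were tested. In HSL119 replicate 2, 619 panel genes exceeded that value, against 531 and 546 in replicates 1 and 3. The other groups' libraries had 523 to 567. HSL119 replicate 2 thus stood apart near background, which limits changes near the floor in HSL119.

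The 3 HSL119 libraries lay apart from the other 12 on the component that carried 59.2% of the variance. The component with 25.4% of the variance ordered CTL, then knockdown replicates 1 and 2, then knockdown replicates 3 and 4. Within each knockdown line, replicates 3 and 4 differed from 1 and 2 by more than 2-fold in 43 genes of KD1 and 65 of KD2, against 3 genes in CTL. Libraries 1 and 2, and libraries 3 and 4, were near-duplicates in CTL and KD1 and may be technical repeats. P-values rest on 1 spread per gene, pooled over all 4 groups. That spread mixes differences between near-duplicates with those of knockdown replicates 3 and 4 from 1 and 2. CDKN1C, for instance, differed between these replicates by -1.88 in KD1 and -2.50 in KD2, against -0.009 in CTL. The pooled spread enters the tests of HSL119 against CTL too. The typical gene also shifted against CTL on the deposited scale, with a median log2 difference of 0.41 for HSL119, 0.43 for KD1 and 0.41 for KD2. Changes are therefore given on the log2 scale relative to that median. A gene is said to have risen or fallen only where limma's adjusted p was under 0.05 in one direction on 5 scalings, each with all libraries and with near-duplicate pairs averaged.

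**Figure D1:**
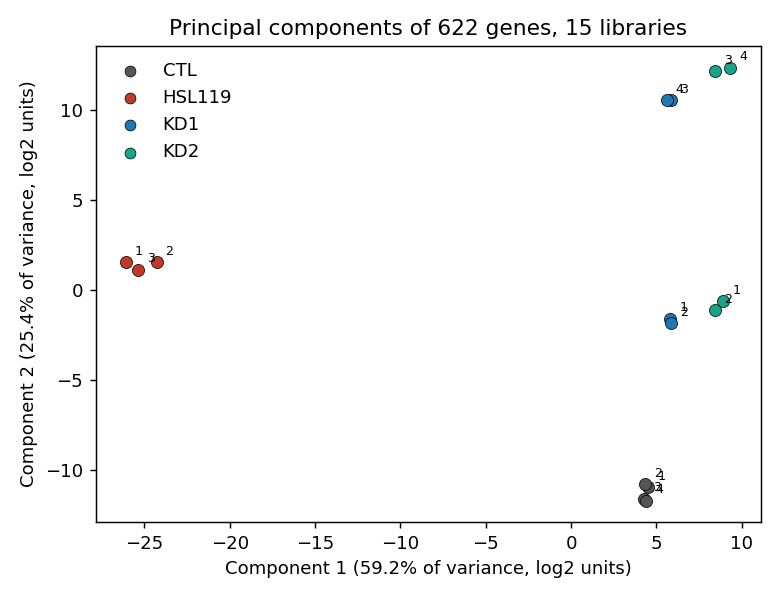
Each point is a library, placed by its scores on components 1 (59.2% of the variance) and 2 (25.4%) of the log2 values of 622 genes, scaled by median of ratios. Points are coloured by group and numbered by replicate. The HSL119 libraries lie on the far left and knockdown replicates 3 and 4 at the top.

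HSL119 was compared with CTL to ask which panel genes differ in cells given the compound. NRCAM, a neuronal adhesion molecule, rose by 3.09 (SE 0.15). The transcription factor MAF rose by 3.56 (SE 0.32) and the interleukin 1 receptor antagonist IL1RN by 3.54 (SE 0.25), both from CTL means under the floor of 20, with CTL replicate 3 the lowest for IL1RN at a log2 of 2.97. The histone methyltransferase gene NSD1 rose by 2.97 (SE 0.25). SRPX fell by 5.14 (SE 0.29), to an HSL119 mean under the floor, and the intermediate filament gene VIM fell by 4.38 (SE 0.13). TGFB2, a TGF-beta ligand, fell by 4.18 (SE 0.36). The protease inhibitor SLPI fell by 4.09 (SE 0.12), and F3, the tissue factor that starts coagulation, fell by 3.91 (SE 0.21). Also among the 10 largest rises were DUSP4 (2.82), CACNA1D (2.69), ASPM (2.65) and ANXA9 (2.49), and the other largest falls were SPRY4 (-4.96, to a mean under the floor), FOSL1 (-4.74), FOS (-4.44), DUSP6 (-4.17) and RARRES3 (-3.88). In every gene named here all 3 HSL119 libraries lay on that side of the CTL mean, as the naming rule requires. The highest adjusted p among them was 0.0146, for FOS (SE 1.32), and the lowest 9.5e-12, for VIM and SLPI. With near-duplicate pairs averaged the adjusted p in limma was 0.0340 for FOS, 7.2e-07 for VIM and 2.2e-06 for SLPI. By limma, 445 genes passed on the deposited values, 300 higher and 145 lower. The split was 212 and 207 with log2 of the linear value plus 1, 144 and 264 when centred on sample medians, 227 and 185 after quantile normalization and 206 and 215 by median of ratios. On every scaling, 126 genes rose and 113 fell.

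**Figure D2:**
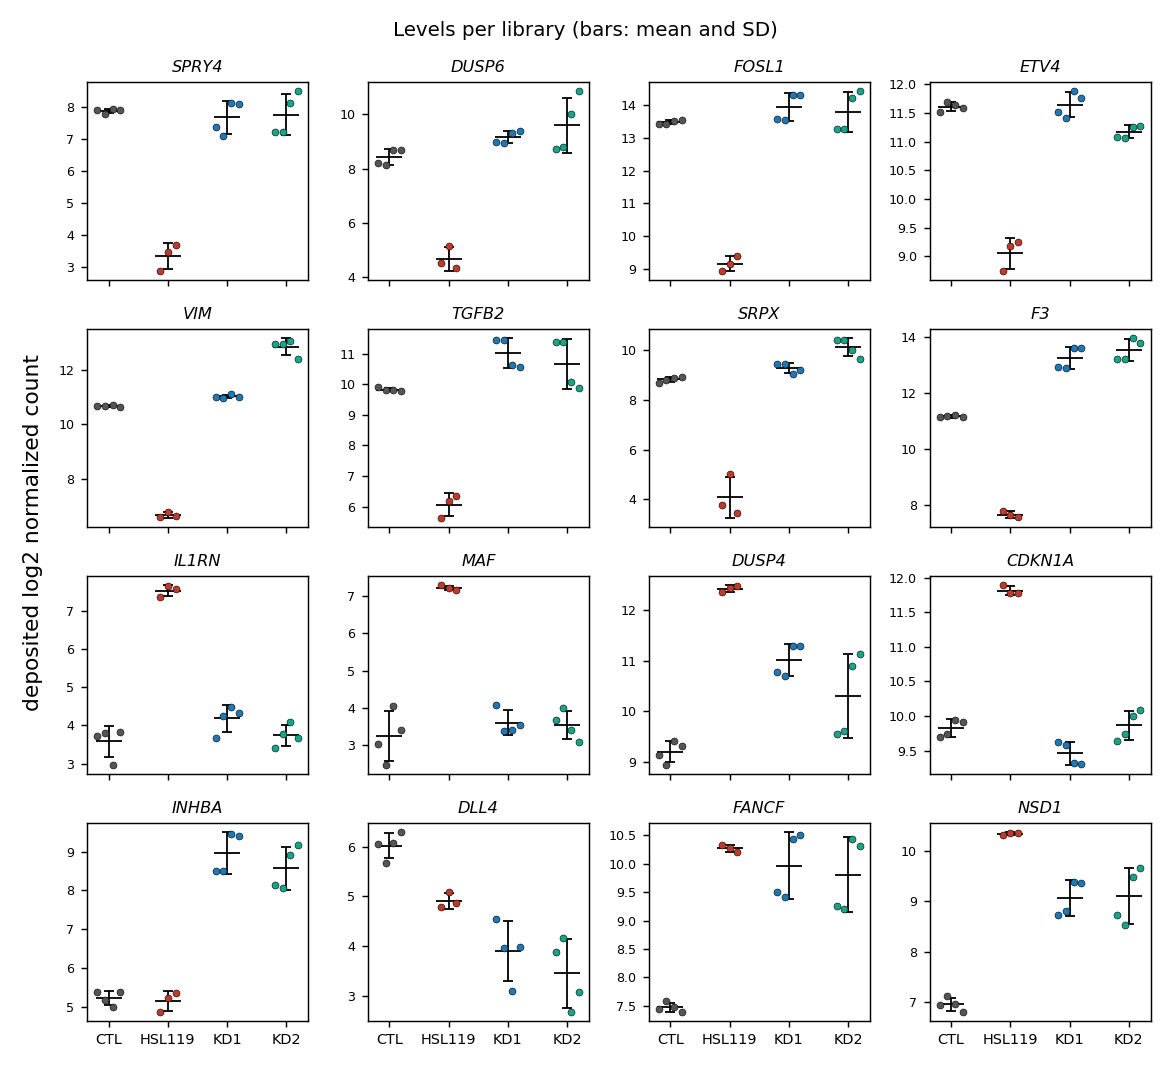
Deposited log2 normalized counts of 16 genes, 1 point per library, for CTL (n = 4), HSL119 (n = 3), KD1 (n = 4) and KD2 (n = 4), with bars for the mean and SD. VIM averaged 10.68 in CTL and 6.71 in HSL119, and INHBA 5.24 in CTL and 8.96 in KD1.

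Of 14 genes of the MAPK pathway and its feedback, 8 fell and 3 rose in HSL119, over all genes and adjusted over the list alone. The feedback inhibitors SPRY4, DUSP6 and SPRY1 (-1.09, SE 0.27) fell. So did the transcription factors FOSL1, FOS, JUN (-2.82, SE 0.43), ETV4 (-2.96, SE 0.13) and MYC (-1.98, SE 0.13). The phosphatase DUSP4, the inhibitor SPRY2 (1.17, SE 0.16) and the kinase MAPK10 (1.81, SE 0.29) rose. MAPK3 (-0.33) and RASGRP1 (-0.64) did not pass on every scaling. The list median was -1.53, and camera gave an adjusted p of 0.0679, with adjusted p = 0.358 with an estimated correlation.

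Of 46 cell cycle and proliferation genes, 14 fell and 4 rose in HSL119, the same numbers adjusted over the list alone. Cyclin E (CCNE1) fell by 1.95 (SE 0.06), and cyclin A (CCNA2) fell by 1.21 (SE 0.06). The ribonucleotide reductase subunit RRM2 fell by 2.42 (SE 0.18), and cyclin D1 (CCND1) fell by 1.84 (SE 0.38). CENPF rose by 1.56 (SE 0.10), CDC25B by 0.90 (SE 0.07), FOXM1 by 0.79 (SE 0.16) and MKI67, the Ki-67 proliferation marker, by 0.63 (SE 0.10). The list's adjusted p in camera was 0.0679, with adjusted p = 0.428 with an estimated correlation. Among 19 p53 targets and cell cycle inhibitors, 4 rose and 3 fell, again the same over the list alone. The inhibitor CDKN1A rose by 1.58 (SE 0.12), CDKN2C by 1.17 (SE 0.09), MDM2, which degrades p53, by 0.88 (SE 0.10) and RB1 by 0.72 (SE 0.09). THBS1 fell by 3.61 (SE 0.31), CDKN1C fell by 2.70 (SE 0.64) and CDKN2D fell by 1.74 (SE 0.38). Of 9 apoptosis genes, none rose and 1 fell, BCL2L1 (-0.74, SE 0.09), which inhibits apoptosis.

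Of 18 mesenchymal and EMT genes, 6 fell and 0 rose in HSL119, as they did over the list alone. Beside VIM and TGFB2, these were TGFB1 (-3.79, SE 0.14), the repressor SNAI2 (-3.40, SE 0.21), the protease MMP14 (-1.84, SE 0.20) and the adhesion receptor CD44 (-1.43, SE 0.05). Camera gave the list an adjusted p of 0.0679, with adjusted p = 0.251 with an estimated correlation. Among 11 epithelial genes, 4 rose and 2 fell. OCLN, of tight junctions, rose by 2.24 (SE 0.10), DSC2, of desmosomes, by 1.85 (SE 0.20), MUC1 by 1.70 (SE 0.13) and E-cadherin (CDH1) by 0.61 (SE 0.05). CLDN1 fell by 2.62 (SE 0.14) and KRT7 fell by 0.95 (SE 0.14). Of 16 luminal and hormone receptor genes, 4 rose, among them CXXC5 (1.43, SE 0.08) and ESR1 (1.11, SE 0.22), and 2 fell, BLVRA (-0.95, SE 0.05) and GPR160 (-0.97, SE 0.14). Of 15 basal genes, 6 rose, among them MIA (2.30, SE 0.31) and KRT14 (1.75, SE 0.37), and 1 fell. These 3 lists gave the same counts adjusted over the list alone, and their adjusted p in camera was 0.768, 0.435 and 0.401.

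Of 8 ERBB receptor, ligand and adaptor genes, 2 rose and 1 fell in HSL119, also over the list alone. ERBB2, which encodes HER2, rose by 1.46 (SE 0.09), EGFR by 0.67 (SE 0.11), and the ligand AREG fell by 1.85 (SE 0.15). Of 11 PI3K-AKT-mTOR genes, 6 rose and 0 fell, and 7 rose when adjusted over the list alone. Among these were the kinase subunit genes PIK3R3 (2.41, SE 0.33), PIK3R1 (1.67, SE 0.14), PIK3R2 (0.84, SE 0.11) and PIK3CA (0.51, SE 0.07), and MTOR (0.51, SE 0.09). Among 21 DNA damage repair genes, 9 rose and 2 fell, also over the list alone. FANCF rose by 2.39 (SE 0.33), BRCA2 by 2.16 (SE 0.32), XRCC2 by 2.09 (SE 0.38), PMS2 by 1.86 (SE 0.09) and BRCA1 by 1.41 (SE 0.20), while RAD54L fell by 1.33 (SE 0.07) and UBE2T fell by 1.37 (SE 0.12). Of 11 transcription and chromatin modifiers, 4 rose and 0 fell, also over the list alone. Beside NSD1 these were the acetyltransferases KAT2B (2.47, SE 0.26), EP300 (1.77, SE 0.07) and CREBBP (1.03, SE 0.14). Camera's adjusted p was 0.768 for the ERBB list, 0.144 for PI3K, 0.109 for repair and 0.0679 for chromatin, and the chromatin list had adjusted p = 0.251 with an estimated correlation.

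Of 7 interferon response genes, 4 fell in HSL119, and 2 did when adjusted over the list alone: OAS3 (-3.27, SE 0.22), CXCL10 (-1.75, SE 0.25), SOCS1 (-1.54, SE 0.36) and ISG15 (-1.03, SE 0.20) made up the 4. Of 15 antigen presentation genes, 5 fell, among them HLA-B (-2.45, SE 0.15) and HLA-C (-0.92, SE 0.08), and 1 rose, HLA-DMA (0.73, SE 0.13). Of 6 NF-kB genes, 3 fell, TNF (-1.53, SE 0.16), NFKBIZ (-2.68, SE 0.35) and IL6 (-2.13, SE 0.35). Among 17 secreted cytokines, chemokines and growth factors, 6 fell and 3 rose, the last being IL1RN, LIF (1.55, SE 0.26) and VEGFA (0.64, SE 0.09). Of 7 checkpoint and tumour-immune ligand genes, PDCD1LG2 (-1.86, SE 0.13) and CD276 (-0.78, SE 0.05) fell and LAG3 (0.91, SE 0.29) rose. Counts were the same over the list alone for these last 4 lists. Camera's adjusted p was 0.109, 0.0732, 0.0679, 0.437 and 0.401 in the order of the 5 lists.

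The remaining lists moved in part. Of 18 Wnt pathway genes, 5 fell and 0 rose, among them the transcription factor LEF1 (-3.26, SE 0.37), TCF7L1 (-2.24, SE 0.19) and WNT7B (-1.74, SE 0.11). Of 21 TGF-beta and BMP genes, 5 fell, among them INHBB (-2.16, SE 0.19) and SMAD3 (-1.91, SE 0.09), and 3 rose, among them TGFBR2 (0.96, SE 0.20). Of 13 JAK-STAT genes, SOCS2 (1.65, SE 0.09) and IL4R (1.15, SE 0.16) rose while LIFR (-1.18, SE 0.10) and SOCS1 fell. Of 12 Notch genes, MAML2 (1.51, SE 0.12) rose and the ligand DLL4 (-1.52, SE 0.36) fell. Of 12 hypoxia and angiogenesis genes, VEGFA and the glucose transporter gene SLC2A1 (0.84, SE 0.09) rose and THBS1 fell. SLC2A1 was also the 1 gene of 8 in the glycolysis list that rose. All 6 lists gave the same counts over the list alone. Camera's adjusted p was 0.0732 for Wnt and between 0.446 and 0.768 for the others. For the JAK-STAT, Notch, glycolysis and p53 lists the direction of camera's test was up while the median lay at -0.11, -0.03, -0.11 and 0.00, and the mean of the p53 list against the rest at -0.28. The CTL means of MAPK10, MIA, KRT14 and LAG3 and the HSL119 means of CXCL10, LEF1 and TCF7L1 also lay under the floor, which limits the precision of their differences. Across the 23 lists camera passed 0 in HSL119 against CTL, with 9 at an unadjusted p under 0.05. Fry, which asks whether a list's genes move one way and not whether they move more than others, passed 20, and 20 by median of ratios.

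KD1 was compared with CTL to ask what the first shRNA line changes. The labels list puromycin for both knockdown lines and do not say whether CTL cells received it. Effects of the shRNA and of puromycin therefore cannot be told apart against CTL. INHBA, the activin A subunit, rose by 3.29 (SE 0.28), or 9.80-fold, and the linker histone gene HIST1H1C by 2.40 (SE 0.24). FANCF, of the Fanconi anaemia repair complex, rose by 2.06 (SE 0.30), the transmembrane protein gene HEG1 by 2.04 (SE 0.10) and the Notch coactivator MAML2 by 2.03 (SE 0.12), with replicate 2 of KD1 the lowest at a log2 of 8.13. The ephrin ligand EFNA5 rose by 1.76 (SE 0.25) and ASPM, of the mitotic spindle, by 1.70 (SE 0.23). ID2, an inhibitor of differentiation factors, fell by 3.70 (SE 0.75), with replicates 3 and 4 of KD1 lower than 1 and 2 by a difference of -3.01. DLL4, a Notch ligand, fell by 2.55 (SE 0.33), to a mean under the floor, and the growth factor receptor FGFR3 fell by 1.69 (SE 0.19). Their adjusted p in limma ran from 4.4e-10 for HEG1 to 0.00206 for ID2. With near-duplicate pairs averaged it was 0.00019 for HEG1 and 0.0407 for ID2. All 4 KD1 libraries lay on that side of the CTL mean, as the naming rule requires. PECAM1 (2.15, from a CTL mean under the floor) and DKK1 (1.75) passed on the deposited values but not on every scaling with pairs averaged. So did SNAI1 (-2.89), CDKN1C (-2.18), SOCS1 (-1.77), BAIAP3 (-1.72), HDAC5 (-1.48), CDKN2D (-1.41) and TTYH1 (-1.27).

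Of 21 DNA damage repair genes, 4 rose in KD1 and 0 fell, and 7 rose when adjusted over the list alone. Beside FANCF these were BRCA2 (1.60, SE 0.30), BRCA1 (1.36, SE 0.19) and PMS2 (0.68, SE 0.09). The list's median difference between replicates 3 and 4 and replicates 1 and 2 was 0.29 in KD1 and 0.15 in KD2. Among 46 cell cycle genes, CENPF (0.99, SE 0.09), CDC6 (0.82, SE 0.09), MELK (1.12, SE 0.19) and MKI67 (0.59, SE 0.09) rose, and CCNE1 fell by 0.79 (SE 0.06). Over the list alone, 5 rose and 2 fell. None of the 14 MAPK genes or the 18 mesenchymal and EMT genes passed on every scaling in KD1, while 1 EMT gene rose when adjusted over the list alone. HLA-E (-1.22, SE 0.17) fell among 15 antigen presentation genes, and 0 fell over the list alone. PDCD1LG2 rose by 1.33 (SE 0.12). By limma, 373 genes passed on the deposited values, 334 higher and 39 lower. The split was 238 and 60 with log2 of the linear value plus 1, 114 and 186 when centred on sample medians, 132 and 142 after quantile normalization and 151 and 136 by median of ratios. With near-duplicate pairs averaged 208 genes passed, and on every scaling 43 rose and 7 fell, a total of 50 that was 15 without HSL119 replicate 2 and 23 without HSL119 replicate 3. Leaving out an HSL119 library changes only the estimate of spread that all groups share, not the difference of either knockdown line from CTL. The total on every scaling was 92 with knockdown replicates 1 and 2 alone, and 197 with 3 and 4 alone. Camera passed 0 of 23 lists, with 3 at an unadjusted p under 0.05, and fry passed 21 on the deposited scale and 7 by median of ratios.

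KD2 was compared with CTL to ask the same of the second shRNA line. INHBA rose by 2.92 (SE 0.28), HIST1H1C by 2.39 (SE 0.24) and S100A7, a calcium-binding protein of stressed epithelium, by 2.32 (SE 0.35). The Wnt antagonist DKK1 rose by 2.28 (SE 0.37), EFNA5 by 2.15 (SE 0.25), MAML2 by 2.07 (SE 0.12) and F3 by 1.96 (SE 0.19). DLL4 fell by 2.98 (SE 0.33), to a mean under the floor, and FGFR3 fell by 2.32 (SE 0.19). The receptor NOTCH3 fell by 1.88 (SE 0.34) and FHL1 fell by 1.83 (SE 0.21). Their adjusted p in limma ran from 2.3e-09 for MAML2 to 0.00185 for NOTCH3. With near-duplicate pairs averaged it was 0.00043 for MAML2 and 0.0279 for NOTCH3. All 4 KD2 libraries lay on that side of the CTL mean, as the naming rule requires. Replicates 3 and 4 of KD2 were lower than 1 and 2, though, by a difference of -1.47 for NOTCH3, -1.03 for FHL1, -1.25 for DLL4 and -0.75 for FGFR3. PECAM1 (2.33), STC1 (2.03), SNAI1 (-2.96), ID2 (-2.96), CDKN1C (-2.35), LEPR (-1.96), HDAC5 (-1.91) and BAIAP3 (-1.83) passed on the deposited values but not on every scaling with pairs averaged.

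The EMT genes VIM (1.73, SE 0.12), SNAI2 (1.25, SE 0.20) and CDH2 (0.74, SE 0.13) rose in KD2 among 18 tested, as they did over the list alone. VIM was lower in KD2 replicate 4, at 12.38, than in the other KD2 libraries. Of 7 interferon response genes, CXCL10 (1.43, SE 0.23), OAS3 (1.14, SE 0.20) and ISG15 (1.10, SE 0.19) rose, and over the list alone 3 rose and 1 fell. Of 21 repair genes, 5 rose, among them FANCF (1.92, SE 0.30), BRCA2 (1.67, SE 0.30) and BRCA1 (1.35, SE 0.19), and 6 did over the list alone. Of 17 secreted factors 4 rose, INHBA, CXCL10, TNFSF10 (1.08, SE 0.21) and PDGFB (0.74, SE 0.09), also over the list alone, with TNFSF10 rising from a CTL mean under the floor. SPRY2 (1.14, SE 0.14) was the 1 MAPK gene of 14 that rose. By limma, 386 genes passed on the deposited values, 336 higher and 50 lower. The split was 275 and 72 with log2 of the linear value plus 1, 127 and 205 when centred on sample medians, 147 and 165 after quantile normalization and 180 and 152 by median of ratios. With pairs averaged 251 passed, and on every scaling 54 rose and 15 fell, a total of 69 that was 45 without HSL119 replicate 3 and 219 with knockdown replicates 3 and 4 alone. Camera passed 0 of 23 lists, with 2 at an unadjusted p under 0.05, and fry passed 23 on the deposited scale and 11 by median of ratios.

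The knockdown lines were compared with each other to ask whether the 2 shRNAs differ. VIM was the 1 gene to pass on every scaling, lower in KD1 than in KD2 by a log2 difference of -1.80 (SE 0.12). Its adjusted p in limma was 3.3e-07 with all libraries and 0.00049 with pairs averaged. VIM no longer passed on every scaling without KD2 replicate 3. On the deposited values with all libraries, the epidermal growth factor family ligand EREG (1.41, SE 0.33), FHL1 (1.17, SE 0.21), FGF13 (1.13, SE 0.19), CACNA2D3 (0.89, SE 0.10) and ARNT2 (0.78, SE 0.17) were higher in KD1. S100A7 (-1.75, SE 0.35), the cytokine IL1B (-1.39, SE 0.22), TLR4 (-1.27, SE 0.29) and PLCE1 (-1.04, SE 0.27) were lower. None of these 9 passed with pairs averaged. Camera passed 4 lists of 23. Cell cycle genes were higher in KD1 by a mean of 0.13 relative to the rest of the panel, and interferon response genes lower by a mean of -0.49, both with an adjusted p of 0.0056 and on all 5 scalings. Secreted factors (mean -0.31, adjusted p 0.0412, 4 scalings) and NF-kB genes (mean -0.53, adjusted p 0.0473, 3 scalings) were lower on some scalings only. On the deposited scale no list passed with the correlation estimated from the data: adjusted p = 0.363 with an estimated correlation for the cell cycle list, 0.072 for interferon, 0.363 for secreted factors and 0.541 for NF-kB. On 1 of the 5 scalings the interferon list passed with an estimated correlation. By limma 57 genes passed on the deposited values, 31 higher in KD1 and 26 lower, and 21 and 28 by median of ratios. With pairs averaged 1 passed, with replicates 1 and 2 alone 117 and with 3 and 4 alone 129. Deviations of equal replicate number correlated between KD1 and KD2, but those of unequal number were not compared. The difference of replicates 3 and 4 from 1 and 2, shared by both lines, may give such correlations without pairing by number. A replicate block gave 62 genes in the fit of all libraries and 145 in a fit of the 2 lines alone. The latter counts near-duplicate libraries as separate pairs.

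HSL119 was compared with the mean of KD1 and KD2 to ask directly whether the compound and the knockdowns differ. The labels list puromycin for the knockdown lines and none for HSL119. An effect of puromycin therefore cannot be told apart from that of the shRNA here either. F3 was lower in HSL119 by a log2 difference of -5.66 (SE 0.19), or 50.6-fold, SRPX by -5.52 (SE 0.26), VIM by -5.14 (SE 0.11) and TGFB2 by -4.72 (SE 0.32). S100A7 was lower by -5.05 (SE 0.33), and the HSL119 means of S100A7 and SRPX lay under the floor. MAF was higher in HSL119 by 3.72 (SE 0.28), IL1RN by 3.65 (SE 0.22), FGFR3 by 3.15 (SE 0.18) and the nuclear receptor NR4A3 by 2.89 (SE 0.71), MAF and IL1RN both from knockdown means under the floor. Adjusted p in limma ran from 1.5e-13 for VIM to 0.00314 for NR4A3. With pairs averaged these were 2.5e-08 and 0.0153. NR4A3 also varied within groups: replicates 3 and 4 differed from 1 and 2 by -2.75 in KD1, -2.08 in KD2 and 1.56 in CTL. Of 46 cell cycle genes, 19 were lower in HSL119 and 2 higher, among them RRM2 (-2.64, SE 0.16), CCNE1 (-1.14, SE 0.05) and CDC6 (-1.09, SE 0.09). Of 11 chromatin modifiers 8 were higher and 0 lower, among them KAT2B (2.09, SE 0.23), HDAC6 (1.01, SE 0.08) and HDAC10 (0.86, SE 0.07). Both lists gave the same counts over the list alone. They were the 2 lists of 23 that passed camera, with an adjusted p of 0.0106 and 0.0118, each on 4 of 5 scalings. Neither held when the correlation was estimated: adjusted p = 0.244 with an estimated correlation for the cell cycle list and 0.123 for chromatin.

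Of 14 MAPK genes, 7 were lower in HSL119 than in the knockdowns and 2 higher, and 9 were lower over the list alone. DUSP6 (-4.62, SE 0.37), FOSL1 (-4.63, SE 0.25) and SPRY4 (-4.31, SE 0.29) were among the lower ones. Of 18 EMT genes 6 were lower, among them SNAI2 (-4.48, SE 0.19), and of 11 epithelial genes 6 were higher and 2 lower, with MUC1 at 2.22 (SE 0.11). Of 18 Wnt genes 9 were lower and 1 higher, with LEF1 at -4.08 (SE 0.33) and DKK1 at -2.96 (SE 0.35). The HSL119 means of SPRY4, LEF1 and DKK1 lay under the floor. The EMT, epithelial and Wnt lists gave the same counts over the list alone. The CDK inhibitor CDKN1A was higher by 2.23 (SE 0.11) and ERBB2 by 1.21 (SE 0.08). By limma 411 genes passed on the deposited values, 191 higher in HSL119 and 220 lower. The split was 152 and 273 with log2 of the linear value plus 1, 178 and 244 when centred on sample medians, 234 and 185 after quantile normalization and 209 and 208 by median of ratios. On every scaling 138 were higher and 153 lower. The 90% interval of the difference lay within 1.5-fold either way for 154 genes (24.8% of 622) and wholly beyond it for 220 (35.4%). For KD1 against KD2 the same counts were 385 (61.9%) and 10. These intervals come from the fit with all libraries and are not adjusted for the number of genes. If near-duplicate pairs are technical repeats, the intervals may be too narrow, and they were not computed with pairs averaged.

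Genes that moved in one direction in all 3 comparisons with CTL were then counted. On every scaling 20 rose and 2 fell in all 3, against 6.89 and 0.545 expected if the genes that moved in HSL119 were drawn without regard to the 34 that rose and 3 that fell in both knockdowns. That expectation leaves out the shared controls. The total of 22 was 8 without HSL119 replicate 2 and 13 without HSL119 replicate 3. With 1 control pair for HSL119 and the other for the knockdowns, 0 passed in all 3 either way, as at most 1 gene rose in both knockdowns. With all libraries alone on every scaling, and control replicates 1 and 2 for HSL119, 32 rose and 7 fell in all 3, against 12.96 and 3.50 expected in the same way. With control replicates 3 and 4 for HSL119 these were 28 and 6, against 11.97 and 2.89. The 20 included repair genes, FANCF, BRCA1, BRCA2, PMS2 and MUS81 (1.19, 0.63 and 0.63 in HSL119, KD1 and KD2), and the chromatin genes NSD1 (2.97, 1.68 and 1.73) and EP300 (1.77, 0.66 and 0.69). Signalling genes among them were EGFR, IL4R, ROCK2, ADCY9, BMPR1A, MAP2K4 and EFNA5. The others were ASPM, CENPF, HIST1H1C, CXXC5, ADAM12 and MAML2. DLL4 and the creatine kinase gene CKB (-2.58, -1.11 and -1.08) fell. On the deposited values 171 genes were higher and 19 lower in all 3, a total of 190, against 143.7 and 7.46 expected in the same way. By median of ratios the split was 78 and 61, against 41.1 and 39.1. XRCC2 (2.09, 1.54 and 1.53), SNAI1 (-2.69, -2.89 and -2.96), CDKN1C (-2.70, -2.18 and -2.35), SOCS1 (-1.54, -1.77 and -1.47) and CDKN2D (-1.74, -1.41 and -1.59) were among these 190 but did not pass on every scaling in both knockdowns. On every scaling 4 genes moved opposite ways in HSL119 and KD1 and 14 in HSL119 and KD2, the latter including VIM, SNAI2, OAS3, CXCL10 and ISG15. In 4 genes the direction was opposite to HSL119 in both knockdowns. CAV1 (-1.61, 0.52 and 0.62), F3 (-3.91, 1.66 and 1.96) and PDCD1LG2 (-1.86, 1.33 and 1.12) fell in HSL119 and rose in both knockdowns, and FGFR3 (1.08, -1.69 and -2.32) did the reverse. All comparisons with CTL rest on the same 4 control libraries.

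**Figure D3:**
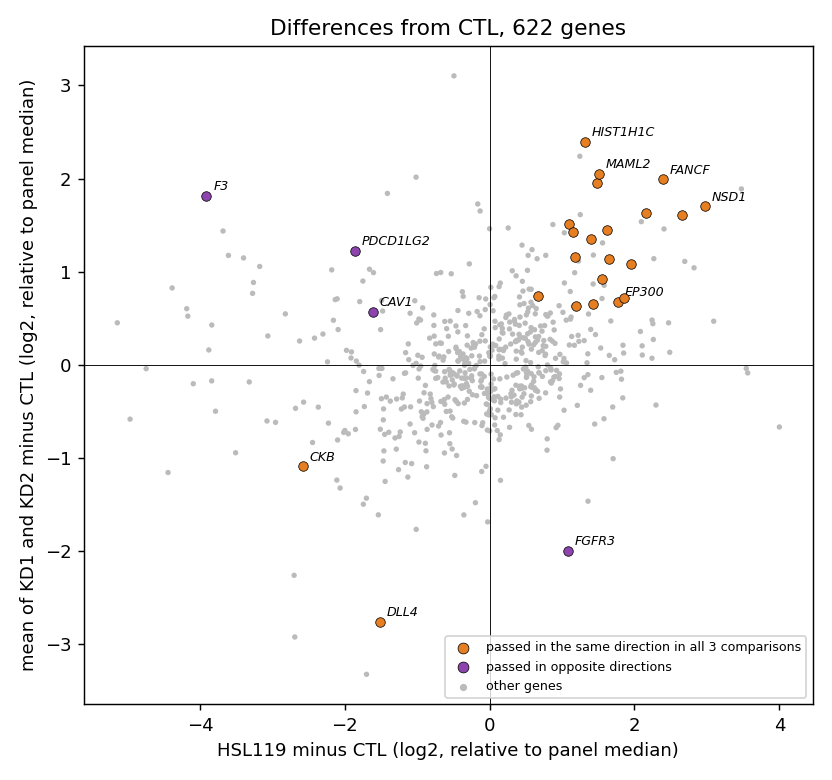
Each point is 1 of 622 genes, with its log2 difference from CTL, relative to the panel median, in HSL119 on the horizontal axis and averaged over KD1 and KD2 on the vertical axis. Orange marks the 22 genes that passed in one direction in all 3 comparisons and purple the 4 that passed in opposite directions.

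Across the 622 genes, which are not independent replicates, the log2 differences of HSL119 and KD1 had a Pearson r of 0.318 and a Spearman rho of 0.350. For HSL119 and KD2 these were 0.176 and 0.241, and for KD1 and KD2 0.893 and 0.872. Shared controls alone gave unchanged simulated groups a mean r of 0.454, 0.465 and 0.503, with a highest r of 0.626, 0.614 and 0.671. The r of HSL119 with either knockdown lay below that mean, while that of KD1 and KD2 exceeded the highest. Simulated groups differ by noise alone, so shared controls weigh more in their r than in groups with real changes. An r of HSL119 below that mean therefore neither shows nor argues against a shared response. The simulation leaves out what KD1 and KD2 libraries of equal number share, their deviations from the group mean correlating at 0.594 to 0.764, which would raise r between unchanged knockdowns too. Both lines also had puromycin, per the labels, so their r does not single out an effect shared by the shRNAs. The covariance was 0.279, 0.170 and 0.448, against a simulated mean of 0.0254, 0.0260 and 0.0263 and a simulated highest value of 0.0456, 0.0436 and 0.0470. With the 4 controls split between the comparisons, r averaged 0.298, 0.161 and 0.846. With the replicate block, r was 0.345, 0.207 and 0.893.

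**Figure D4:**
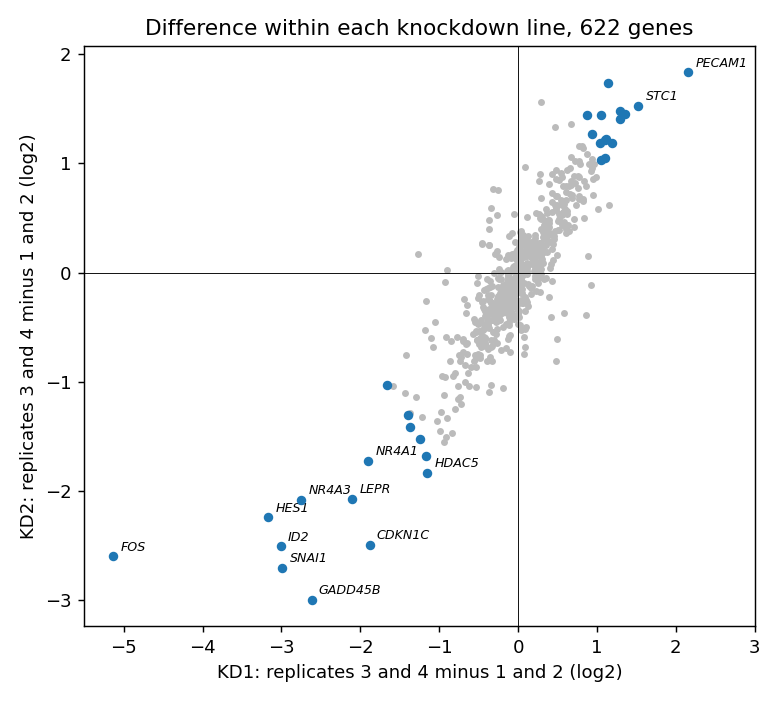
Each point is 1 of 622 genes, with the log2 difference of replicates 3 and 4 from replicates 1 and 2 in KD1 (horizontal axis) and KD2 (vertical axis). Values were scaled by median of ratios. Blue marks the 15 most negative and the 15 most positive genes by the mean of both lines. FOS lay at -5.13 and -2.60, and PECAM1 at 2.16 and 1.84.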

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

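The tests on knockdown replicates, gene length, controls split by pair, controls run apart, the MAPK genes, and splits with pairs or sets as units were chosen only after the results were seen, while the counts over other splits of the libraries and the covariance under shared controls were set before.

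Libraries far from the rest of their group were sought in CTL, KD1 and KD2, by the gap to the nearest library over the group's range. The search took the total counts, the median log2 value and the genes with the largest or shared changes under the naming rule. Genes named only as list members, and the HSL119 group, were not searched. Of 165 sets of 4 values, 5 exceeded Dixon's critical value, against 8.25 expected by chance, which marks about 1 in 20 sets. That expectation assumes independent libraries, which near-duplicate pairs may not be. FOS in KD2 replicate 3 was 5.97, against 9.74 to 10.37 in the other KD2 libraries (ratio 0.858). VIM in KD2 replicate 4 was 12.38, against 12.94 to 13.05 (0.836). HEG1 in KD2 replicate 3 was 10.36, against 10.04 to 10.09 (0.845), MAML2 in KD1 replicate 2 was 8.13, against 8.27 to 8.30 (0.858), and IL1RN in CTL replicate 3 was 2.97, against 3.73 to 3.83 (0.879).

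Effects differed between groups by direct test in 57 genes for KD1 against KD2 on the deposited values, and in 291 genes for HSL119 against the mean of the knockdowns on every scaling. Other splits of the same libraries were counted. For HSL119 against CTL, 1 of 35 splits, the real one, gave as many as 445 genes. The highest other gave 308 and placed CTL replicate 3 with the HSL119 libraries. For KD1 and KD2 against CTL, 1 of 35 gave as many as 373 and 386, and the highest others gave 2 and 0. For HSL119 against the 8 knockdown libraries taken as a single group, 1 of 100 drawn splits gave as many as 401, with 105 the highest other. With libraries as units, chance can be excluded at 0.05 for these 4. Near-duplicate libraries may not be separate units, however. With pairs as units KD1 or KD2 against CTL allows 3 splits and HSL119 against CTL 10, too few for a share under 0.05, and the real splits gave 208, 251 and 390 genes with 0 the highest other. HSL119 against the 4 knockdown pairs allows 35, of which 1 gave as many as 382, with 117 the highest other. Knockdown pairs of equal number vary together, though, and as 2 sets they leave 10 splits, again too few, with 359 genes in the real one and 0 the highest other. For KD1 against KD2, 2 of 35 splits gave as many as 57, so chance cannot be excluded over all of them. The split of replicates 1 and 2 from 3 and 4 gave 337 genes, which points to a structure of the libraries. The 8 splits that part every replicate number, as the real one does, are too few for a share under 0.05, and the highest other gave 0. The real split gave 62 genes with the replicate block over all libraries, 145 with it in the 2 lines alone and 1 with pairs averaged.

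Knockdown replicates 3 and 4 differed from 1 and 2 alike in both lines, with a correlation across genes of 0.863. FOS (-5.13 and -2.60), SNAI1 (-2.99 and -2.71), GADD45B (-2.62 and -3.00) and ID2 (-3.01 and -2.51) were lower in 3 and 4, and PECAM1 (2.16 and 1.84) and STC1 (1.52 and 1.53) higher. A batch shared by every group's libraries 3 and 4 would carry the difference into CTL, but the higher of its correlations with the knockdowns was -0.139. A difference in depth is also argued against, since among genes above a linear value of 500 the SD of the difference was at least 4.63 times that of CTL. Handling or culture of the knockdown cells alone may account for it, and cannot be told apart from a biological difference such as passage or density, since the labels describe neither.

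The 20 genes that rose in HSL119 and both knockdowns may share a response. Over all 622 genes the covariance of HSL119 and KD1 was 0.279, against a highest value of 0.0456 in 200 simulated sets with shared controls. Those sets held no near-duplicate pairs, and a covariance over all genes cannot test these 20. With the controls split by pair, 32 or 28 genes rose in all 3 with all libraries alone, though 0 with pairs averaged too. Chance values of the shared controls were therefore not excluded for the 20. Gene length as the whole cause is argued against, since 17 of the 20 still passed on every scaling in all 3 once each library's linear trend on length was removed. A control group handled or run apart from all treated libraries stays open, since all 20 rest on the same 4 CTL libraries and the deposited log2 offset itself differs between CTL, HSL119 and the knockdowns. In 19 of the 20, knockdown replicates 3 and 4 were higher than 1 and 2, so the unexplained difference within the knockdowns runs along these genes too.

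In HSL119, 8 MAPK pathway and feedback genes fell. A changed background in the HSL119 libraries would spare genes well above it, but 4 members above a linear value of 100 in both groups fell on every scaling: FOSL1, JUN, ETV4 and MYC. The difference that sets knockdown replicates 3 and 4 apart was also tested on the 8 genes, with a median of -0.0474 in KD1 and 0.17 in KD2. The medians go opposite ways. FOS (-5.13 and -2.60), JUN (-1.66 and -1.03) and SPRY1 (-0.66 and -0.37) were lower in 3 and 4 in both lines. SPRY4 (0.78 and 1.00), FOSL1 (0.65 and 0.96), DUSP6 (0.29 and 1.56) and ETV4 (0.27 and 0.09) were higher in both. MYC was lower in KD1 (-0.37) and higher in KD2 (0.26). This explanation stays open for the 8 as a set, though SPRY4, FOSL1, DUSP6 and ETV4 moved against their fall in HSL119. Reduced MAPK signalling under HSL119 is a hypothesis consistent with the fall of SPRY4, DUSP6 and ETV4, though DUSP4 and SPRY2 rose, and no protein or phosphorylation was measured.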

How the results depend on the processing

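Pair averaging, knockdown replicates taken in part, median of ratios, split controls, the count of 22, edgeR, DESeq2, the block in the knockdowns alone and the demand for every scaling were chosen after seeing the data. The 5 gene counts on deposited values were 445, 373, 386, 57 and 411, in the order HSL119, KD1 and KD2 against CTL, KD1 against KD2, and HSL119 against the knockdowns. They moved by over 1.5 times for KD1 with a fold of 1.5 (240) and pairs averaged (208), for KD2 with pairs averaged (251), and for KD1 against KD2 with arrayWeights (374, estimates that did not converge), a fold of 1.5 (24), adjusted p under 0.01 (9), the 2 groups alone (9), the replicate block in these alone (145), knockdown replicates 1 and 2 (117) or 3 and 4 (129) and pairs averaged (1). Fewer genes pass a stricter threshold and fewer libraries enter averaged fits by construction; otherwise the cause was not tested. Genes passing on every scaling moved for KD1 (50) to 81 with arrayWeights, 9 at 0.01, 92 with knockdown replicates 1 and 2 and 197 with 3 and 4, for KD2 (69) to 15 at 0.01 and 219 with replicates 3 and 4, and for KD1 against KD2 (1) to 8 and 14 with these replicates; the cause was not tested. Those passing alike in HSL119, KD1 and KD2 (22) moved to 3 at 0.01, 46 and 98 with these replicates and 0 with controls split by pair; the cause was not tested. The 190 shared genes became 117 after quantile normalization, 121 with a fold of 1.5 and 122 with pairs averaged; the cause was not tested. Lists passing camera (0, 0, 0, 4 and 2) became 3, 1 and 1 against CTL without the filter. For HSL119 against CTL they became 2 when centred on sample medians and with 1 or 10 added to the linear value, and 1 with the compared groups alone, knockdown replicates 1 and 2 or 3 and 4. For KD1 and KD2 they became 2 and 1 with replicates 1 and 2. For KD1 against KD2 they became 2 with a floor of 50, quantile normalization or replicates 1 and 2, and 0 with an estimated correlation. For HSL119 against the knockdowns they became 0 after quantile normalization and with an estimated correlation. Fry, which asks another question, passed 20, 21, 23 and 21 lists outside KD1 against KD2, and 20, 7, 11 and 22 by median of ratios. For the camera changes the cause was not tested. The correlation of HSL119 and KD1 (0.318) moved to 0.279 without the filter, 0.345 with the replicate block, 0.251 with knockdown replicates 1 and 2 and 0.298 with split controls. That of HSL119 and KD2 (0.176) moved to 0.102 with arrayWeights and to 0.0865 and 0.216 with knockdown replicates 1 and 2 or 3 and 4. That of KD1 and KD2 (0.893) moved to 0.710 with arrayWeights, 0.811 with replicates 1 and 2 and 0.846 with split controls; beyond the noise that shared controls add, the cause was not tested.

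With each library left out, the deposited counts ran from 399 to 448, 328 to 387, 360 to 392, 29 to 66 and 371 to 423. KD1 against KD2 was 29 without KD1 replicate 2, 30 without KD1 replicate 3 and 35 without KD1 replicate 1 or KD2 replicate 3. On every scaling the ranges were 203 to 244, 15 to 59, 45 to 70, 0 to 1 and 251 to 294, and 8 to 24 for the 22, with 8 without HSL119 replicate 2 and 13 without replicate 3, with KD1 at 15 without HSL119 replicate 2 and 23 without replicate 3, KD2 at 45 without HSL119 replicate 3, and VIM lost from KD1 against KD2 without KD2 replicate 3. Shared genes ran from 171 to 194, the correlations from 0.302 to 0.325, 0.146 to 0.196 and 0.866 to 0.897, and passing lists were 0, 0, 0, 2 to 4, and 2. Count models on CTL and the knockdowns gave 142 higher and 136 lower genes in KD1 by edgeR and 150 and 146 by DESeq2. In KD2 these were 175 and 149, and 176 and 164, and for KD1 against KD2 21 and 36, and 40 and 44. In the 3 comparisons 181, 225 and 46 genes passed both edgeR and limma in one direction. For the 421 gene results chosen by the naming rule, recomputed under 31 settings, 12605 values kept their call, 361 no longer passed and 71 changed direction, these in 37 results and all under rescaling. Leaving out list members that did not pass on every scaling left 266 results, with 0 changes of direction and 63 values no longer passing. A gene that passes on every scaling keeps its direction there by definition. This 0 was therefore largely fixed by the choice and shows no stability. Centring on housekeeping genes was not run, since none are identified. Low counts limit genes near the floor of 20, such as MAF in CTL.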

Other observations

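The values by gene and by replicate given here were chosen after the results were seen, and the markers of other cell types before. Beyond the lists tested as groups, BNIP3, a mitophagy receptor and the 1 measured gene of the autophagy list, differed by -0.60 (SE 0.08) in HSL119, -0.20 (SE 0.07) in KD1 and -0.17 (SE 0.07) in KD2, and passed on every scaling in none of them. Among the 3 measured stress response genes, VEGFA rose in HSL119 by 0.64 (SE 0.09). EIF2AK3, a kinase of the unfolded protein response, differed by 0.79 (SE 0.31) and the stress cytokine GDF15 by -0.11 (SE 0.31) there without passing on every scaling. Against the mean of the knockdowns, EIF2AK3 was higher in HSL119 by 1.66 (SE 0.28) and GDF15 by 1.11 (SE 0.28), both on every scaling. CD68, a lysosomal glycoprotein used as a macrophage marker, fell by 2.23 (SE 0.21) in HSL119, from a mean linear value of 389.6 in CTL to 88.3.

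Other genes lower in knockdown replicates 3 and 4 than in 1 and 2 were HES1 (-3.17 in KD1 and -2.24 in KD2), NR4A3 (-2.75 and -2.08), NR4A1 (-1.90 and -1.72), CDKN1C (-1.88 and -2.50) and LEPR (-2.10 and -2.07). The p53 target and cell cycle inhibitor list had a median difference of -0.60 in KD1 and -0.69 in KD2, against -0.0002 in CTL. LFNG (1.11 and 1.23) and CCND1 (0.88 and 1.44) were higher in replicates 3 and 4.

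Markers of other cell types were mostly near the floor of 20. The median linear value in CTL was 36.3 for 2 T cell genes, 11.1 for 7 NK and cytotoxic genes, 26.2 for 4 macrophage and myeloid genes, 17.3 for 5 fibroblast genes and 14.6 for 8 endothelial genes. In HSL119 the T cell median was 57.8, with CD8A at 92.6, and the fibroblast median 21.1. In KD1 these medians were 46.9 and 14.8, and in KD2 47.6 and 15.4. The fibroblast marker PDGFRA was abundant in every group, with means of 304.3 in CTL, 235.5 in HSL119, 336.6 in KD1 and 335.2 in KD2. The endothelial marker PECAM1 had means of 43.1 in HSL119, 119.4 in KD1 and 128.1 in KD2, and other endothelial genes stayed near the floor.

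Of the 20 genes that rose in HSL119 and both knockdowns, 3 no longer passed on every scaling once each library's linear trend on gene length was removed, as their differences shrank by more than their SE did. EGFR went from 0.67 (SE 0.11) to 0.36 (SE 0.09) in HSL119 and from 0.67 (SE 0.10) to 0.51 (SE 0.09) in KD2. MAP2K4 went from 1.15 (SE 0.22) to 1.01 (SE 0.20) in KD1, and ADAM12 from 1.10 (SE 0.24) to 0.67 (SE 0.21) in HSL119. The median gene length was 105219 bases for the 20 and 28312 for all 622.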
